A study of Mus musculus with 4 samples.

How the data were processed

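Polyadenylated RNA was measured by sequencing in 4 libraries of mouse heart, each labelled as a wild-type C57BL/6J animal, male, at 12 weeks of age. The label for tissue names the heart as a whole, while the labels' protocols state that the apex of the ventricles was frozen and that RNA was taken from it with Trizol. Per the labels' protocols, RNA with poly(A) tails was captured on oligo(dT), fragmented chemically and made into single-end libraries that do not keep the strand. Because strand was not kept, reads of a gene and of an overlapping antisense gene cannot be told apart.

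The deposited files hold raw counts of reads per gene, whole numbers that were not normalized. The submitters' processing notes name the mm10 genome build and the tools Bowtie2, TopHat, TopHat2 2.0.10, HTSeq, DESeq and edgeR, without saying which step each was used for. The gene annotation and the counting mode are not given in the sources used here. Each file lists 23420 gene symbols and 5 rows that name no gene. Those rows were left out of library sizes and tests. The rows for reads outside genes and for unaligned reads were listed at 0 in each file. The rest held 9.16 ± 0.145% of the listed reads (SD, n = 4), of which reads assigned to more than 1 gene made up 0.824 ± 0.00778% and alignments that were not unique 8.33 ± 0.147%. Reads that align to several near-identical copies therefore drop out of the counts, and levels of genes with close paralogs or processed pseudogenes are uncertain.

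The 4 libraries form 1 group, so no comparison between groups was made. Nothing in the labels says outright that each library came from its own animal, and the p-values measure the spread between these samples, which may in part be technical. Libraries are numbered as in the submitters' titles. Library-scaled counts (CPM, counts per 1e6) were computed per library over all counted genes, with library sizes scaled by trimmed mean of M-values (TMM) factors of 1.00, 1.00, 0.986 and 1.01. Depth was between 10523709 and 15359296 gene counts per library. A count of 0 allows a level of up to 3 counts, worth 0.193 to 0.289 CPM depending on the library. Limits of 95% for single libraries are exact Poisson limits for counts and exact Clopper-Pearson binomial limits for shares. They cover counting error only, since reads without molecular identifiers are not independent molecules.

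Genes were tested for a spread between libraries above that of other genes of similar abundance. This used edgeR 4.0.16 in R 4.3.3 with an intercept as the only term, TMM factors, a fitted dispersion trend and the quasi-likelihood fit with a robust prior. Each gene's quasi-dispersion was divided by the trend, and this variance ratio was set against an F distribution on 3 residual and 7.42 prior degrees of freedom, upper tail. Genes with a mean of at least 1 CPM were tested, and a Benjamini-Hochberg adjusted p under 0.05 was called more variable. On simulated counts for 12358 genes with 200 changed genes in each of 5 simulations, the test recovered 26.3% of genes changed 2-fold in 1 or 2 libraries, 88.7% of those changed 4-fold and 99.4% of those changed 8-fold. An average of 10.4 of 153 calls were of unchanged genes, and 0.6 genes were called where no gene had been changed. The simulated dispersions were drawn from the test's own fitted trend and prior, so these rates hold only under that model.

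A total of 33 gene lists and 18 gene pairs were fixed before the data were examined. For each list the CPM of its members was summed per library. For lists with at least 5 tested members, the median log2 variance ratio was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins. That percentile describes these libraries and is not a p-value across animals, because members of a list can move together. The 13 mitochondrially encoded genes had 0 entries under the symbols searched, so they were not analysed here and shares of counts leave them out. For each pair, the log2 ratio of counts, with 0.5 added to each, was formed within a library and tested over the 4 libraries with a two-sided exact sign-flip permutation test, whose smallest p is 0.125.

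Pairs of libraries were compared with a chi-square test of their counts over genes with at least 10 counts in sum, and with correlations across genes of log2(CPM + 1). Genes named in the text followed a fixed rule: the 20 with the highest mean CPM, the 20 called genes of at least 5 CPM with the largest variance ratio, up to 3 leading and up to 5 called members of each list, both genes of each pair, and the sex-linked genes. A gene that this rule would name is not reported here. Genes named outside that rule are said to have been chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, the assembly that mm10 denotes. By symbol or by an older synonym listed in RefSeq, 22994 of the 23420 genes (98.2%) were matched to it.

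Alternatives were other scaling factors (the median-of-ratios factors of DESeq2 1.42.0, or library totals), no filter or a mean of at least 5 CPM, a prior that was not robust, limma 3.58.1 with a mean-variance trend, the dispersion outliers of DESeq2, each library left out in turn, and pair ratios per kilobase of exon or with nothing added to the counts. Shares of counts were also recomputed without haemoglobin genes, and after seeing the data without Rn45s. Alternatives chosen after seeing the data left out Rn45s and Lars2, left out genes on X and Y, or kept libraries 1 and 4 alone. Figures were drawn with matplotlib 3.10.9.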

Results

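The series profiled the polyadenylated RNA of the unmanipulated adult heart in C57BL/6J mice, the standard inbred laboratory strain. Per the labels' protocols, the RNA was taken from the apex of the ventricles. The series holds 4 libraries of a single group, all labelled male and 12 weeks old, and no treated or control group. The comparisons open to it are between genes within a heart and between the hearts. Libraries 1 to 4 held 14412049, 13919367, 10523709 and 15359296 reads assigned to genes. At this depth 16052 ± 213 genes per library had at least 1 count (SD, n = 4), 12345 ± 38.7 reached 1 CPM, and 5973 genes had 0 counts in all 4 libraries.

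Transcripts of the contractile apparatus led the messenger RNAs counted here. None of the 13 mitochondrially encoded genes had an entry under the symbols searched, so the shares below leave them out. Myh6, the adult alpha myosin heavy chain (chromosome 14, 54941921 to 54966927), took 4.99 ± 0.477% of all gene counts (SD, n = 4). Below it stood Ttn, the giant sarcomere protein titin, at 19913 ± 3041 CPM, the oxygen-binding protein Mb at 13214 ± 664 CPM and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 11576 ± 544 CPM. Tnnt2 stood at 10158 ± 272 CPM, Actc1 at 9462 ± 159 CPM, Tpm1 at 9299 ± 284 CPM and Myl2 at 7053 ± 423 CPM. The most abundant entry of all was Rn45s, the precursor of ribosomal RNA, at 12.8, 14.1, 11.9 and 12.3% of counts in libraries 1 to 4, although the RNA had been selected for poly(A) tails. The binomial limits of 95% on the library 1 share ran from 12.778 to 12.813%, so the libraries differed by more than counting error. Lars2, a mitochondrial leucyl-tRNA synthetase, had the next largest share after Myh6, at 2.18 ± 0.411%. It stood 200.1-fold above the most abundant of 16 other mitochondrial aminoacyl-tRNA synthetase genes, a comparison made after seeing the data. Whether all counts of Lars2 came from its messenger RNA was not tested.

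The remaining genes among the 20 most abundant were again mostly of muscle and mitochondria. They included the sarcomere genes Mybpc3 (5674 ± 177 CPM), Tnni3 (5243 ± 216 CPM) and Myl3 (4009 ± 207 CPM), and the calcium release channel Ryr2 (4577 ± 114 CPM). Subunits of ATP synthase stood at 4137 ± 25.4 CPM for Atp5a1 and 4101 ± 57.7 CPM for Atp5b, the ADP/ATP carrier Slc25a4 at 4090.4 ± 119 CPM and the fatty acid binding protein Fabp3 at 4033 ± 259 CPM. Pde4dip had 4408 ± 48.1 CPM and the long non-coding RNA Malat1 6037 ± 952 CPM. The 10 most abundant genes held 28.0 ± 1.09% of counts and the 100 most abundant 45.7 ± 0.731% (SD, n = 4). Without Rn45s in the total, a setting chosen after seeing the data, the 10 most abundant genes held 18.2%.

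Summed over the fixed lists, sarcomere and Z disc genes accounted for 14.6% of counts, 145888 ± 9608 CPM (SD, n = 4), with all 24 members at 1 CPM or more. Nuclear-encoded oxidative phosphorylation summed to 31188 ± 1227 CPM over 42 members. Creatine and high-energy phosphate genes summed to 23576 ± 498 CPM, calcium handling to 23413 ± 608 CPM, the tricarboxylic acid cycle to 20034 ± 619 CPM, fatty acid oxidation to 17332 ± 548 CPM and glycolysis with glucose uptake to 16111 ± 409 CPM. Within these lists the lipase Lpl had 3699 ± 69.0 CPM, Ogdh of the tricarboxylic acid cycle 3658 ± 184 CPM, Aldoa of glycolysis 3320.4 ± 168 CPM and the cardiac form of cytochrome oxidase subunit VIa, Cox6a2, 2170 ± 388 CPM. Ion channels and connexins summed to 3319.8 ± 99.7 CPM. Cardiac transcription factors came to 2390 ± 70.5 CPM and adrenergic and muscarinic signalling to 3641 ± 46.3 CPM. Heat shock and protein folding genes came to 8517 ± 588 CPM, most of it from the small heat shock protein Hspb7 at 2698 ± 239 CPM, Hsp90ab1 at 1758 ± 170 CPM and Hspa8 at 1284 ± 220 CPM.

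Markers of other cell types were far below those of muscle. Smooth muscle and pericyte markers summed to 4451 ± 114 CPM, of which the muscle intermediate filament Des, also made by cardiomyocytes, gave 2580 ± 91.6 CPM. Fibroblast and matrix genes summed to 4279 ± 54.4 CPM, with Gsn at 1497 ± 49.3 CPM and Sparc at 547 ± 27.9 CPM, and endothelial genes to 3065 ± 156 CPM, with the water channel Aqp1 at 497 ± 97.0 CPM. Macrophage markers summed to 481 ± 33.7 CPM, adipocyte markers to 998 ± 102 CPM and lymphocyte and neutrophil markers to 283 ± 10.4 CPM. The antigen presentation gene Cd74, which macrophages also make, gave 272 ± 12.0 CPM of the latter. Of the adipocyte sum, Pnpla2 gave 487 ± 41.5 CPM and Fabp4, which is in the endothelial list too, 412 ± 61.1 CPM. Neural and Schwann cell markers (27.8 ± 2.77 CPM), epicardial markers (18.6 ± 2.37 CPM) and fast skeletal muscle genes (82.4 ± 5.38 CPM) were low. Genes of lung, thymus and liver summed to 3.63 ± 0.841 CPM (n = 4), with 1 of 17 members at 1 CPM or more.

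In this RNA, which per the labels' protocols came from the apex of the ventricles, genes of the atria differed widely in level. The atrial light chain Myl7 had 1, 7, 3 and 2 counts in libraries 1 to 4 and sarcolipin, Sln, chosen after its values were seen, 1, 3, 0 and 2 counts. The atrial and conduction list summed to 1431 ± 88.6 CPM, with 17 of 25 members at 1 CPM or more, and holds Clu (592 ± 54.5 CPM), Pam (473 ± 42.2 CPM) and the natriuretic peptide Nppa (139.8 ± 9.27 CPM). Cell cycle genes summed to 131 ± 11.3 CPM, replication-dependent histones to 84.0 ± 4.15 CPM and interferon response genes to 667 ± 44.8 CPM, of which B2m gave 182 ± 18.3 CPM. Long non-coding RNAs summed to 7344 ± 1091 CPM, nearly all of it Malat1 and Neat1 (1029 ± 145 CPM). Red cell genes summed to 45.2 ± 6.19 CPM (n = 4), a figure without haemoglobin, whose entries Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, chosen after their values were seen, had 0 counts in all 4 libraries.

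**Figure D1:**
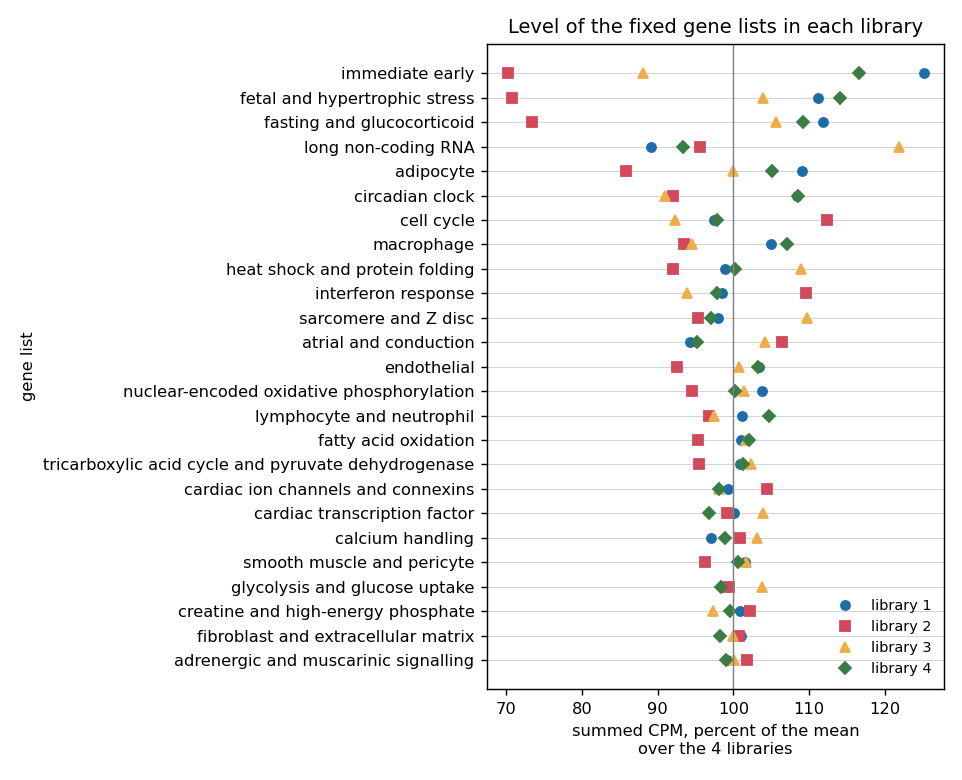
Summed CPM of each fixed gene list with a mean of 100 CPM or more, the sex-linked list left out, drawn per library as a percentage of the mean over the 4 libraries (horizontal axis), with 1 row per list and 1 symbol per library. Lists of metabolism sit close to 100, and the immediate early, stress, and fasting and glucocorticoid lists spread widest of those drawn, with library 2 lowest in each of these 3.

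In the fixed pairs, the first gene, usually the form typical of adult heart or muscle, was the more abundant in 4 of 4 libraries for 16 of 18 pairs. Myh6 exceeded the fetal and slow myosin Myh7 by 278-fold, a log2 ratio of 8.12 ± 0.17 (SD, n = 4), and cardiac actin Actc1 exceeded skeletal actin Acta1 by 39.1-fold. The widest gaps were those of ventricular Myl2 over atrial Myl7 (30006-fold), of cardiac troponin I, Tnni3, over the slow skeletal form Tnni1 (20963-fold, on 2 to 4 counts of Tnni1) and of Atp2a2 over the skeletal muscle pump Atp2a1 (8681-fold, on 12 to 21 counts). Myl3 exceeded Myl4 by 1359-fold and Tpm1 exceeded Tpm2 by 410-fold. With the second gene at 1 to 7 counts, the Myl2 to Myl7 ratio ran from 12160 to 66670 between libraries and its size is loose. Because the protocols name the ventricular apex as the source, this ratio may not describe a heart with its atria.

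Most pairs of energy metabolism followed the same order. The muscle enolase Eno3 exceeded Eno1 by 211-fold, the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 21.3-fold, Slc25a4 exceeded Slc25a5 by 19.8-fold and Cox6a2 exceeded Cox6a1 by 25.4-fold. Folds were 5.92 for Pgam2 over Pgam1, 3.33 for Ldhb over Ldha, 2.26 for Cox7a1 over Cox7a2, 1.89 for Hk2 over Hk1 and 1.42 for the potassium channels Kcnd2 over Kcnd3. Cpt1b, the muscle form of the enzyme that admits long-chain fatty acids to mitochondria, ran the other way: its counts were 0.141 times those of the liver form Cpt1a, lower in 4 of 4 libraries. The natriuretic peptides Nppa and Nppb differed by less than the spread between libraries, with Nppa higher in 2 of 4 (log2 ratio 0.35 ± 0.62, SD, n = 4, exact sign-flip permutation p = 0.5).

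Each of the other 17 pairs had the smallest two-sided p that an exact sign-flip permutation test allows with 4 libraries, 0.13 both before and after Benjamini-Hochberg adjustment over 18 pairs, so none could pass 0.05. Per kilobase of exon no pair changed direction, but folds moved: Ldhb over Ldha to 7.01, Eno3 over Eno1 to 653, Cpt1b over Cpt1a to 0.320 and Myl2 over Myl7 to 9079. Cpt1b is uncertain: in GENCODE M21, 81.4% of its exon bases (chromosome 15, 89416405 to 89425863) are shared with other genes. The entry BC090627 (89416405 to 89429696), chosen after its values were seen, spans Cpt1b and has 100% of its exon bases shared. It had 0 counts in all 4 libraries. Whether this sharing lowered the counts of Cpt1b was not tested, since the annotation and counting mode are not given in the sources used here. Eno1, Pgam1, Cox6a1, Cox7a2 and Slc25a5 belong to families with processed pseudogenes, and their counts are uncertain for that reason.

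**Figure D2:**
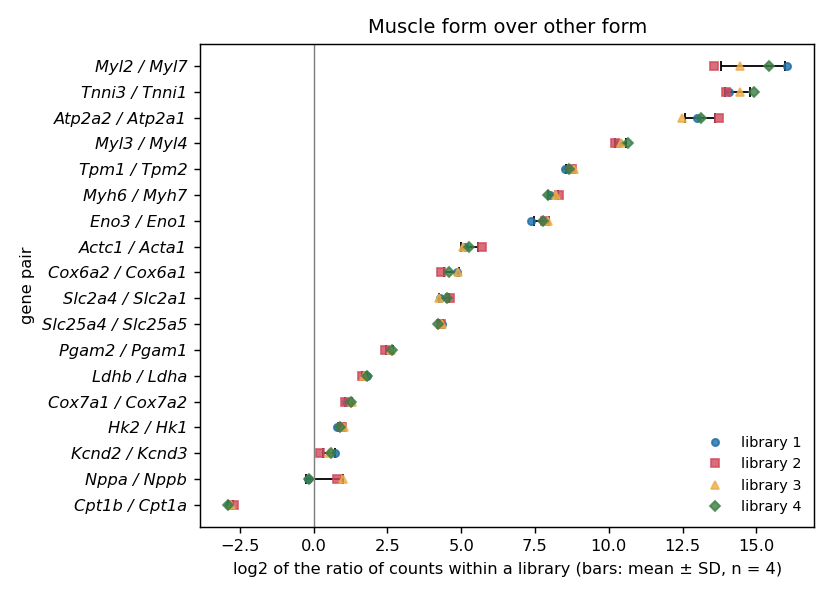
Log2 ratio of counts of the first over the second gene of each fixed pair (horizontal axis), with 1 symbol per library, a row per pair, and bars for mean ± SD over 4 libraries. Of the 18 pairs, 16 lie right of 0 in 4 of 4 libraries, Cpt1b over Cpt1a lies left of it, and Nppa over Nppb straddles it.

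Sex-linked transcripts split the 4 libraries labelled male. Xist, the RNA that coats the inactive X of female cells (chromosome X, 103460366 to 103483254), had 5, 1897, 1806 and 19 counts in libraries 1 to 4, or 0.346, 136, 174 and 1.22 CPM. Y-linked genes ran the other way. Ddx3y had 341, 0, 1 and 437 counts, Kdm5d 169, 0, 1 and 195, Eif2s3y 163, 0, 0 and 201, and Uty 43, 0, 0 and 59. Values in libraries 2 and 3 therefore went against their label, while those in libraries 1 and 4 did not. Exact Poisson limits of 95% on Xist were 0.112 to 0.808 CPM in library 1 and 130.3 to 143 CPM in library 2. The antisense partner Tsix had 0, 2, 0 and 3 counts. In edgeR's quasi-likelihood test for spread between libraries, 5 of the 5 tested members were called, also 5 when adjusted over the list alone, with adjusted p from 1.24e-05 for Xist to 0.0298 for Uty. With a prior that was not robust, with limma and without library 3, 4 of the 5 were called.

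**Figure D3:**
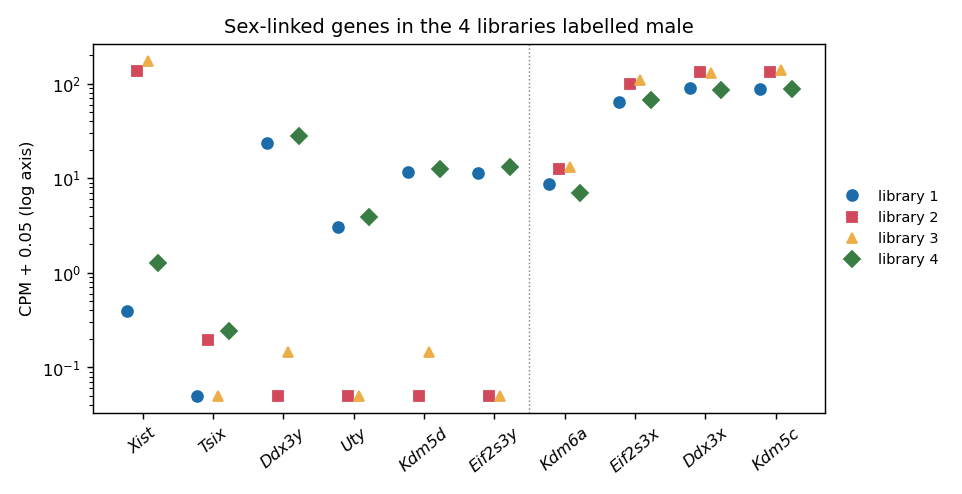
CPM of sex-linked genes in each library, with 0.05 added for the log axis (vertical); symbols stand for libraries 1 to 4 and a dotted line parts the fixed list from X-linked genes chosen after the data were seen. Xist lies at 136 and 174 CPM in libraries 2 and 3 and at 0.346 and 1.22 CPM in libraries 1 and 4, and Ddx3y, Uty, Kdm5d and Eif2s3y lie at 0 or 1 count in libraries 2 and 3.

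The libraries were alike in the bulk of their genes, and libraries 1 and 4 were closest. Across 12358 tested genes, the correlation of log2(CPM + 1) was 0.996 for libraries 1 and 4 and between 0.988 and 0.991 for the other 5 pairs. Genes are not independent replicates. Over genes with at least 10 counts in sum, the chi-square per degree of freedom was 2.22 for libraries 1 and 4, and 10.2 (libraries 1 and 2), 7.72 (1 and 3), 12.6 (2 and 3), 11.8 (2 and 4) and 6.81 (3 and 4) for the others. Each pair thus differed by more than the counting error of reads. Repeat libraries of a single RNA could do so too, so these values do not show that the libraries came from separate animals. The biological coefficient of variation over all 4 was 9.99%. Fitted for single pairs after seeing the data, it was 3.50% for libraries 1 and 4 and between 9.36 and 12.5% for the rest, including 11.1% for libraries 2 and 3.

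Most cardiac genes were steady. The median coefficient of variation over tested genes was 9.55%, with 3.79% at the 10th and 24.4% at the 90th percentile, and 6471 of 12358 genes (52.4%) stayed under 10%. These values cover all 4 libraries and so include any difference that goes with the split in sex-linked transcripts. Steady genes included the mitochondrial ATP synthase subunit Atp5a1 (0.613%), Pde4dip (1.09%), citrate synthase, Cs (1.37%), and Actc1 (1.68%).

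Against that background, 55 genes were more variable between libraries than genes of similar abundance (edgeR, adjusted p under 0.05), 6 of them on X or Y and 49 elsewhere or unplaced. Most were low in library 2 and high in libraries 1 and 4. The stress-responsive cardiac repressor Ankrd1 (chromosome 19, 36111961 to 36120099) had 1369.9, 540.2, 1171 and 1431 CPM in libraries 1 to 4 (adjusted p = 0.0118). Ctgf, a matrix growth factor, had 157, 50.5, 128 and 143 CPM, the receptor Ephb1 67.8, 12.4, 31.0 and 64.1 CPM, the alcohol dehydrogenase Adh1 42.4, 7.69, 16.3 and 46.8 CPM, and the protease inhibitor Timp4 54.1, 9.70, 27.2 and 54.8 CPM. The metallothionein Mt2 had 43.6, 8.77, 17.9 and 40.8 CPM, Fam117b 49.0, 15.95, 22.5 and 55.5 CPM, and 8430408G22Rik, now called Depp1, 76.5, 22.9, 87.3 and 78.4 CPM.

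Other genes broke that order. Txnip, an inhibitor of thioredoxin that responds to glucose (chromosome 3, 96557957 to 96561883), was highest in library 3, with 322, 198, 881 and 359 CPM (adjusted p = 0.00322). Gdpd3 had 25.9 CPM in library 2 against 1.18, 0.674 and 1.03 CPM in libraries 1, 3 and 4 (adjusted p = 0.00274), and Plekha7 28.0 CPM in library 2 against 3.39, 2.79 and 2.96 CPM (adjusted p = 0.00413). Both lie on chromosome 7, Gdpd3 at 126766334 to 126775649 and Plekha7 at 116123485 to 116308376. The adjusted p of these sentences are from edgeR's quasi-likelihood fit. Of the 55 genes, 38 were lowest in library 2. That count includes Eif2s3y, Uty and Gbp1, the last chosen after its values were seen, which had 0 counts in libraries 2 and 3 alike. The share over all tested genes was not computed. Libraries 1 and 4 were the highest 2 for 36 of the 55, a count made after the data were seen, and for 20.5% of all tested genes. Of the 49 called genes elsewhere or unplaced, libraries 1 and 4 were the highest 2 for 31 and libraries 2 and 3 for 7. The unplaced Erdr1, chosen after its values were seen, is among the 7. Over all tested genes libraries 2 and 3 were the highest 2 for 18.3%. In some of the 31, such as Ankrd1 and Ctgf, library 2 stood lowest with library 3 nearer to libraries 1 and 4.

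The count rested on the libraries and on the prior. It was 258 with no filter on low counts and 129 as the dispersion outliers of DESeq2. It fell to 10 with a prior that was not robust, and to 6, none of them among the 55, in libraries 1 and 4 alone. Without library 2 the count was 69, 39 of them shared, and Ankrd1, Ctgf, Fkbp5, Per1, Plekha7 and 8430408G22Rik were no longer called, while Gdpd3 fell under a mean of 1 CPM and was not tested; without library 3 Txnip was not (adjusted p = 0.0804, edgeR).

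**Figure D4:**
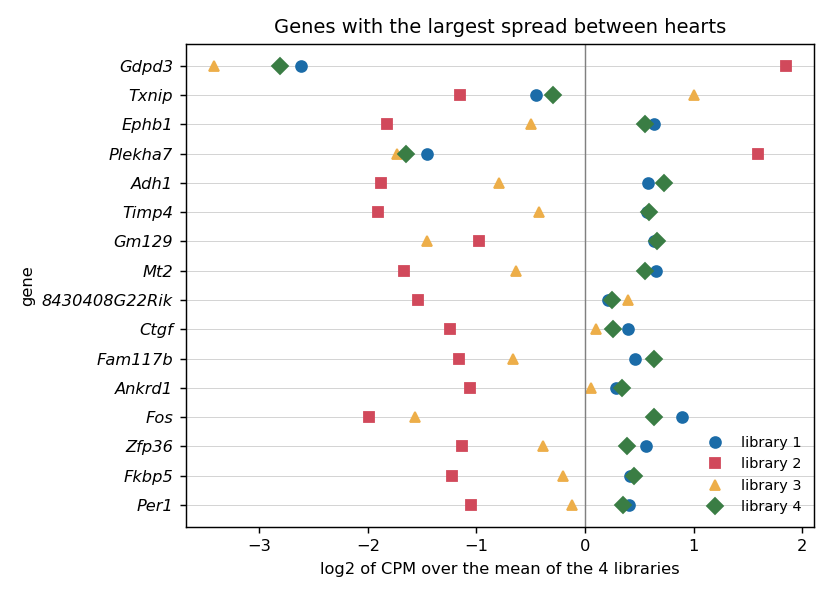
Log2 of CPM over the mean of the 4 libraries (horizontal axis) for the 16 genes outside the sex-linked list among the 20 named variable genes, a row per gene and 1 symbol per library. Library 2 lies lowest for most rows, Gdpd3 and Plekha7 stand high in library 2 alone at 25.9 and 28.0 CPM, and Txnip stands high in library 3.

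Immediate early genes, which cells switch on within minutes of a stimulus, were the fixed list with the widest spread outside the sex-linked one. Their sum was 924, 518, 650.1 and 861 CPM in libraries 1 to 4, 1.78-fold between highest and lowest. Of 22 tested members, 5 were called over all genes and 13 when adjusted over the list alone. With a prior that was not robust edgeR called 0 (13 at an unadjusted p under 0.05), while limma called 5 and DESeq2 had 6 as dispersion outliers. Fos had 17.5, 2.37, 3.18 and 14.7 CPM, Zfp36 78.4, 24.3, 40.9 and 69.8 CPM, Jun 86.2, 41.0, 41.3 and 79.5 CPM, Dusp1 136, 58.7, 82.1 and 138 CPM, and Btg2 66.9, 28.7, 32.1 and 70.6 CPM. Each of these 5 called genes was lower in libraries 2 and 3 than in libraries 1 and 4, as seen after the test. Egr1, chosen after its values were seen, at 60.7, 33.8, 57.1 and 60.2 CPM, was not called over all genes (adjusted p = 0.161, edgeR). The median log2 variance ratio of the list was 3.30, at percentile 100 of its random lists.

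Genes of fasting and glucocorticoid action moved in part with them. The list summed to 2544, 1670, 2402 and 2484 CPM, and 8 of 25 tested members were called, 14 when adjusted over the list alone. Without library 2 the calls were 4, and with a prior that was not robust edgeR called 0 (15 at an unadjusted p under 0.05), against 8 by limma and 10 by DESeq2. The glucocorticoid target Fkbp5 had 78.8, 25.2, 51.2 and 80.8 CPM, Tsc22d3 106, 49.0, 77.3 and 104 CPM, Ddit4 60.2, 17.2, 51.5 and 52.6 CPM and the metallothionein Mt1 253, 104, 185 and 213 CPM. The fasting genes Pdk4, a brake on pyruvate oxidation (261, 158, 406 and 290 CPM), and Angptl4, an inhibitor of lipoprotein lipase (6.65, 1.37, 15.6 and 5.53 CPM), were instead highest in library 3. The ubiquitin ligase Trim63 stayed between 247 and 269.6 CPM and was not called (adjusted p = 0.995, edgeR). Of the genes in this paragraph, Tsc22d3, Mt1 and Angptl4 were chosen after their values were seen. The median log2 variance ratio was 2.79, at percentile 100.

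Fetal and hypertrophic stress genes summed to 3735, 2379, 3493 and 3835 CPM. Of 16 tested members 3 were called, Ankrd1, Ctgf and Nppb, and 6 when adjusted over the list alone. Nppb, the B-type natriuretic peptide, had 157, 75.7, 77.3 and 154 CPM, while Nppa, Myh7 (179.9 ± 18.8 CPM, SD, n = 4) and Xirp1 (458 ± 20.8 CPM) were not called. The list stood at percentile 99.98, which fell to 79.25 without library 2. In the circadian clock list, 2 of 19 tested members were called, 7 when adjusted over the list alone. Per1 had 201, 73.4, 140.1 and 194 CPM, and Gm129, a clock repressor now named Ciart, 46.9, 15.3, 10.98 and 47.7 CPM. Nr1d1 had 239, 245, 152 and 232 CPM and was not called over all genes. The clock list stood at percentile 100. With a prior that was not robust edgeR called 0 members of the stress and clock lists (6 and 7 at an unadjusted p under 0.05), against 3 and 2 by limma and 4 and 2 by DESeq2.

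Few genes were called in the other lists. A single member was called in the ion channel list (Kcna5, 50.7, 18.1, 22.0 and 48.4 CPM, which is in the atrial list too) and in the endothelial list (Rgcc, 35.9, 13.7, 15.5 and 31.4 CPM). When adjusted over the list alone, 1 ion channel, 3 atrial and 2 endothelial members passed. In lists with no call over all genes, between 0 and 5 members passed when adjusted over the list alone, the 5 being the fibroblast genes Col3a1, Col6a3, Dcn, Fbln1 and Timp3, of which Timp3 alone was not chosen after its values were seen. The endothelial list summed to 3169, 2837, 3089 and 3164 CPM and the macrophage list to 505, 449.7, 455 and 516 CPM, and both were lowest in library 2. Of 28 lists with at least 5 tested members, 18 were at the 95th percentile or above and 1, the tricarboxylic acid cycle, was below the 5th, at 3.97. The latter did not hold with library totals, with no filter, with limma or without library 4, and the list was at 38.84 without library 3. In libraries 1 and 4 alone 2 of 27 lists were at the 95th or above; the immediate early list was still at 100, and the fasting and glucocorticoid list was at 61.2, the clock list at 33.3 and the fetal stress list at 14.3.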

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

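Among 96 values tried in the 4 libraries, 8 had a library whose distance to its nearest neighbour exceeded Dixon's critical share of the range at the 95% level. Chance flags about 1 in 20 such groups of values. That rate does not hold for the 20 called genes among them, which were taken for their spread between libraries; 8430408G22Rik, Gdpd3 and Plekha7 are of this kind. In library 2, the fatty acid oxidation list summed to 16520 CPM against 17510 to 17690 CPM in the others. The fasting and glucocorticoid list summed to 1670 CPM there against 2402 to 2544 CPM. The gene 8430408G22Rik stood at 22.9 CPM in library 2 and at 76.5 to 87.3 CPM elsewhere. Gdpd3 was high in library 2 instead, at 25.9 CPM against 0.674 to 1.18 CPM, as was Plekha7 at 28.0 CPM against 2.79 to 3.39 CPM. Library 3 stood apart in the red cell list, at 35.9 CPM against 47.5 to 49.2 CPM, and in Malat1, at 7448 CPM against 5362 to 5679 CPM. Myl3 was highest in library 1, at 4315 CPM against 3867 to 3943 CPM. None of these values comes with a label that sets the library apart from the other 3, and no biological explanation was tested.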

How the results depend on the processing

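The tests without Rn45s and Lars2, without genes on X and Y and on libraries 1 and 4 alone were chosen after the result was seen. No paired analysis was possible because the series holds a single group. The count of 55 variable genes lay between 38 and 62 with other scaling factors, a mean of 5 CPM, limma, or without Rn45s and Lars2 or X and Y. It was 258 with no filter, 129 as dispersion outliers of DESeq2, 10 with a prior that was not robust and 6 in libraries 1 and 4 alone; the cause was not tested, except that the last has fewer samples. Leaving out libraries in turn gave 39 to 69 genes. Of the 20 named variable genes, 10 were called with the prior that was not robust, 0 in libraries 1 and 4 alone, 16 without X and Y, 13 without library 2, 19 without library 3 and 20 in the other settings. As a fraction, the biological coefficient of variation was 0.0776 to 0.111 with a library left out, lowest without library 2, and 0.0350 in libraries 1 and 4 alone. Levels of gene lists moved by less than 1 SD with both other scaling factors; leaving out a library cannot move a mean of 4 by that much and tests nothing here.

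In libraries 1 and 4 alone, where fewer samples were fitted, 2 lists in place of 18 reached the 95th percentile. Percentiles there were 76.9 for sarcomere, 46.1 for ion channels, 14.34 for fetal stress, 59.2 for heat shock, 33.3 for the clock, 61.2 for fasting and glucocorticoid, 19.3 for fibroblast, 14.35 for endothelial, 44.1 for smooth muscle, 92.7 for macrophage, 72.5 for adipocyte, 54.9 for atrial, 63.2 for fast skeletal muscle, 11.8 for interferon and 92.6 for transcription factor genes. With a library left out, ranges were 45.4 to 99.9 for sarcomere and 75.7 to 100 for heat shock, 90.9 to 99.8 for fibroblast and 41.2 to 99.5 for fast skeletal muscle, each lowest without library 3. They were 81.3 to 100 for ion channels, 79.25 to 100 for fetal stress, 53.7 to 99.85 for endothelial, 84.55 to 98.7 for smooth muscle and 83.4 to 100 for interferon, each lowest without library 2. Without library 4 the atrial list was lowest, 92.9 to 99.9, as was adrenergic signalling, 76.0 to 96.7. Oxidative phosphorylation ranged from 17.1 without library 1 to 99.6 without library 3.

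Smooth muscle was at 94.6 with library totals, 94.3 with no filter and 94.5 with limma. Adrenergic signalling was at 92.4 with library totals, 85.3 with a mean of 5 CPM and 94.2 with limma. Fast skeletal muscle was at 93.9 and oxidative phosphorylation at 95.4 with no filter, the latter at 95.05 without Rn45s and Lars2, and cell cycle at 99.6 with a mean of 5 CPM. The cause was not tested.

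Per kilobase of exon the log2 ratios became 8.475 for Myh6, 15.16 for Tnni3, 12.28 for Atp2a2, 13.15 for Myl2, 11.59 for Myl3, 7.52 for Tpm1, 2.81 for Ldhb, -1.64 for Cpt1b, 1.435 for Hk2, 9.35 for Eno3, 3.803 for Pgam2, 1.998 for Cox7a1, 3.79 for Slc25a4 and 1.40 for Kcnd2, each over its partner, through the exon lengths alone. Without Rn45s the 10 and 100 most abundant genes held 18.2 and 37.8% of counts, since its share left the total. Depth limits the pairs with Tnni1 and Myl7, at 1 to 7 counts.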

Other observations

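Genes of the opening 2 paragraphs and the tests on Y-linked genes, on X-linked genes that escape silencing, on cell types and on libraries 1 and 4 alone were chosen after the result was seen. A few autosomal genes were present in some hearts and nearly missing in others. Gbp1, an interferon-inducible GTPase now named Gbp2b (chromosome 3, 142594847 to 142619179), had 74, 0, 0 and 99 counts in libraries 1 to 4 (adjusted p = 0.0118, edgeR), while its relatives Gbp2 and Gbp3 had 11.2, 15.5, 13.5 and 11.002 CPM and 10.9, 18.1, 9.15 and 10.9 CPM. Gm8615 on chromosome 5 had 2, 84, 75 and 2 counts (adjusted p = 0.0118, edgeR). Gm5779 on chromosome 10 had 87, 4, 2 and 109 counts, with 72.2% of its exon bases shared with another annotated gene. Of the haemoglobin entries, the beta globin Beta-s had counts, at 141, 122, 71.9 and 125 CPM.

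Rrad, a small GTPase that restrains calcium channels, and Egln3, an oxygen-sensing prolyl hydroxylase, were among the 8 called genes whose highest libraries were 2 and 3. They had 96.7, 198, 209 and 97.0 CPM and 40.1, 87.9, 91.1 and 43.0 CPM. Lars2 stood 200.1-fold above the most abundant of 16 other mitochondrial aminoacyl-tRNA synthetase genes, which had means of 5.33 to 109 CPM with a median of 12.9 CPM. No explanation for these values was tested.

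Libraries 2 and 3 carried Xist and almost no Y-linked counts under a male label. Female RNA mixed into male libraries was argued against, since the 4 Y-linked genes summed to at most 0.389% there of the lower sum in libraries 1 and 4. These are the same counts that define the pattern, so they are not a separate test. All 4 of the X-linked genes Kdm6a, Eif2s3x, Ddx3x and Kdm5c, which escape silencing on the inactive X, were higher in each of libraries 2 and 3 than in each of libraries 1 and 4 (Kdm5c at 88.2, 131, 138 and 88.2 CPM), as a wrong sex label would give. A candidate explanation is that these libraries came from female hearts; whether labels, samples or files were exchanged stays open, and loss of the Y with gain of Xist by other means was not tested.

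Libraries 1 and 4 were more alike than any other pair. Depth was argued against, because their correlation across genes was 0.9952 after all libraries were thinned to the smallest total, against at most 0.9899 for other pairs. Genes on X and Y were argued against by 0.9963 without them (at most 0.9916 for others), and GC content and gene length by 0.9965 after their trends were removed (at most 0.9907 for others). A shared sex, litter, dissection day or library batch may underlie the likeness, and the labels separate none of these. These candidates are not a full list. The autosomal genes Gbp1 (74, 0, 0 and 99 counts in libraries 1 to 4) and Gm8615 (2, 84, 75 and 2) split the libraries likewise. Gdpd3 and Plekha7 instead stood apart in library 2 alone. No cause of that split was tested. Sex alone leaves open why libraries 2 and 3 had a coefficient of variation of 11.1% between them.

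Immediate early genes varied more between hearts than matched random lists. The sums of the endothelial, fibroblast, smooth muscle and macrophage lists moved less. Their largest ratio of highest to lowest heart was 1.146, under a bound of 1.2, against 1.783 for the immediate early list. Single genes carry much of these sums: Des gave 2580 of 4451 CPM in smooth muscle and Gsn 1497 of 4279 CPM in fibroblasts. The fibroblast sum was flat, at 1.029, though the spread of its members stood at percentile 99.48. A changed share of these cells is therefore not excluded. Among adipocyte, epicardial, neural, lymphocyte and neutrophil, and red cell lists the largest ratio was 1.37, for red cells, short of 1.783 but above the bound of 1.2. The red cell list held no haemoglobin counts. The beta globin Beta-s, outside that list, had 141, 122, 71.9 and 125 CPM, highest in libraries 1 and 4 and lowest in library 3. A difference in blood content is therefore not excluded. The red cell list was highest in library 2, where the immediate early list was lowest, the epicardial list was highest and the neural list lowest in library 3, and the adipocyte list, at 1.272, had the order of the immediate early list. The endothelial list had that order too, with the smaller ratio of 1.117. Most of the adipocyte sum came from Pnpla2 and from Fabp4, which is in the endothelial list too. That sum thus does not isolate adipocytes, whose share stays open. Library 2 was not the sole source: without it the median log2 variance ratio of the list was 2.048 (3.303 with it), where 95% of random lists lay under 0.2364. Without library 2 edgeR called 7 members in place of 5, while members at an unadjusted p under 0.05 fell from 14 to 10. The percentile, 100 in both, is at its ceiling and does not say how much library 2 added. The 5 called members were each lower in libraries 2 and 3 than in libraries 1 and 4, so a difference tied to the sex that the X and Y transcripts point to stays open. In libraries 1 and 4 alone, alike in those transcripts, the list was still at percentile 100, but its sums were 924 and 861 CPM and edgeR called 0 members (5 at an unadjusted p under 0.05), which does not decide it. The fasting and glucocorticoid, clock and fetal stress lists fell to 61.2, 33.3 and 14.34 in the same setting. Another candidate explanation is the state of each animal or the time between removal and freezing of its heart, to which these genes and the glucocorticoid targets could respond; no label bears on it, and it was not tested further.

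Hearts taken at different times of day might account for the spread of Per1 and Gm129. Genes of opposite phase showed no shift of the size set beforehand. The mean log2(CPM + 1) of Dbp, Nr1d1, Per2 and Per3 minus that of Arntl, Npas2 and Clock differed by at most 0.427 between any 2 hearts. A difference of 2 or more in log2 CPM had been set as the mark of such a shift. The 1 added to each CPM damps differences in genes as low as Arntl and Npas2. Arntl was low in each library, at 1.11, 1.22, 1.83 and 1.67 CPM, and Dbp at 102, 112, 76.6 and 103 CPM. The difference was lowest in library 3, at 3.7, where Gm129 was lowest too, at 10.98 CPM. Per1 was instead lowest in library 2, where the difference was 4.063. Smaller shifts in time were not excluded, and Per1 is a glucocorticoid target as well as a clock gene.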
